A study of Mus musculus with 8 samples.

How the data were processed

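RNA sequencing of whole testes from 8 mice at postnatal day 5 (4 wild type and 4 labelled Dio3KO, 129/SVJ background) was deposited as a single table of transcripts. Per the labels, tissue and source were testis and total RNA was extracted, while the extraction text names hypothalami. FastQC, Novoalign 2.08 and the genome build mm10 are listed in the submitters' processing notes without a role or an order. The counting tool, the gene annotation, the strandedness of the libraries and the test behind the p values are not given in the sources used here.

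The authors deposited, for each transcript, the mean RPKM of each group, that is reads scaled to transcript length and library size and averaged over the group's samples, per the file headers. The same table holds the coefficient of variation of each group and an adjusted p-value for wild type against KO, deposited by the authors, per the file headers. Columns were tied to the groups by name, and 0 columns of per-sample values were left unused, so levels are printed as the authors' means without an SD or n of their own. The table had 147417 lines, in which each transcript stood 3 times with equal values, and 49139 transcripts were left once repeats were dropped. The highest coefficient of variation was 2.00, reached in either group by 2293 transcripts, which is the SD divided by the mean when 1 of 4 samples is above 0. The deposited adjusted p-values ran from 0.0022 to 0.8022. Across 24256 transcripts with both means above 5 RPKM, their rank correlation with an unequal-variance test recomputed from the means and CVs was 0.9988 (Spearman's rho, across transcripts, which are not independent replicates), and 0.9948 with an equal-variance test. Means over all transcripts summed to 1015250 RPKM in wild type and 947625 RPKM in the Dio3KO-labelled group, and 309 transcripts had a mean of 0 in both groups. Depth per sample is unknown, and no counting interval or floor was computed.

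Of 24582 deposited symbols, 18080 were current symbols in RefSeq or in a further list of gene names. Another 2557 were older symbols that led to a current one and 3945 were not matched, 27 of them having been turned into dates. Merging gave 23765 genes, of which 11440 had more than 1 transcript. The transcript with the highest mean level stood for its gene. Transcript identifiers have the form of UCSC known genes and were not in the reference, so coordinates were taken from GENCODE M21 (GRCm38, the same assembly as mm10) by gene symbol. RPKM of transcripts that share exons, paralogs or pseudogenes are not independent, and whether reads were assigned by strand is not stated.

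The design, the gene lists and the alternatives not named below as added were fixed before the data were examined. For a table of group means the design set no test of its own. Genes with a mean of at least 1 RPKM in either group (15225) were listed as changed when the ratio of the means, each with 0.5 RPKM added, was at least 2, and the authors' adjusted p-values were reported beside them with a threshold of 0.05. Ratios are on the log2(RPKM + 0.5) scale, which understates the change of low genes. The standard error of a log2 ratio was computed from the deposited CVs by the delta method, with 4 samples per group. The verbs rose and fell were kept for genes with a deposited adjusted p-value below 0.05.

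The genes named are Dio3, the 12 largest rises and the 12 largest falls of at least 2-fold with a larger mean of at least 2 RPKM, and from each list up to 4 members past the threshold with the smallest p and up to 2 members not past it with the highest level. Predicted genes, pseudogenes, small RNA genes and Y-linked genes were left out of the first part. The rule for a table of means named the fold as the threshold for list members. Because the table proved to hold adjusted p-values, these were used for the list members, a reading settled after the table was seen. Some genes that the rule takes are not reported here. Other genes are said where they appear to have been named after their values were seen.

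Each of the 28 fixed lists was summarised by the median and mean log2 ratio of its measured members and by the place of the median among 10000 random lists of the same size, drawn within 20 bins of mean level. In all, 530 measured genes were in a list and 50 were in more than 1. A moderated test was added after the data were seen. It took the variance of each log2 mean from the deposited CVs, shrank it across genes with limma 3.58.1 (squeezeVar with trend and robust, 6 residual degrees of freedom) in R 4.3.3, and adjusted by Benjamini-Hochberg over all genes and over each list alone. A deposited CV of 0.00 was set to 0.0025. Its statistics also entered limma's preranked camera test with preset correlations of 0.01 and 0.05, adjusted over the 28 lists, and, as a search over gene families, the same test at 0.05 over 218 groups of at least 8 genes that share a symbol stem. The moderated test was tested on simulated data for the comparison of Dio3KO with wild type. With 200 of 15225 genes changed, it recovered 86.6% of 1.5-fold, 95.5% of 2-fold and 97% of 4-fold changes, with 8 false calls among 194. The simulated genes were independent and each had 1 CV for both groups. These rates need not hold for the deposited values, where the test called 6370 genes. For lists, 5% of 200 unchanged lists of 20 genes and 100% of 50 lists shifted by 0.4 (log2) fell outside the central 95% of random lists. The random lists were drawn gene by gene, so this gives no error rate for lists of genes that vary together.

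Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Alternatives were other pseudocounts (0.1 and 1), no filter or a filter of 5 RPKM, centring of the median log2 ratio at 0, a fold of 1.5, and, added after the data were seen, another choice of transcript, every transcript, the moderated test and the second preset correlation. Alternatives that need values per sample were left out.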

Results

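RNA sequencing was used to compare testes of 4 wild-type mice with testes of 4 mice labelled Dio3KO, all on the 129/SVJ background and collected at postnatal day 5. Dio3 encodes the deiodinase that inactivates thyroid hormones, and by its title the study asked which genes of the neonatal testis respond to thyroid hormone. The deposited values were group means in RPKM with the coefficient of variation (CV) of each group, so every level given here is the authors' mean and the value of a single mouse was not used. The number of reads per sample is unknown. After transcripts were reduced to the best expressed one per gene, 15225 genes had a mean of at least 1 RPKM in either group. Adjusted p values are those of the authors' deposited table unless limma is named, and "rose" or "fell" is written only of genes with such a p below 0.05.

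Dio3 itself was higher, not lower, in the Dio3KO-labelled group. Its mean was 0.52 RPKM in wild-type testes (CV 0.20) and 2.95 RPKM in Dio3KO-labelled testes (CV 0.29), with an adjusted p of 0.0408 in the authors' deposited table. The log2 ratio of the means, each with 0.5 RPKM added, was 1.76 ± 0.19 (SE computed from the CVs). The antisense gene Dio3os moved the same way, from 0.22 RPKM (CV 0.28) to 3.90 RPKM (CV 0.19), with an adjusted p of 0.0156 in the authors' deposited table. In the mm10 assembly with GENCODE M21 annotation, Dio3 (ENSMUSG00000075707.5) lies on the plus strand of chromosome 12 from 110279068 to 110281097. Dio3os lies upstream on the minus strand from 110275385 to 110278172, and the annotated exons of both genes share 0 bases. The labels do not say which part of Dio3 was altered, so a transcript from the altered allele is not ruled out and the level of Dio3 does not check the labels. The group is therefore called Dio3KO-labelled throughout, and each direction below rests on that label. Of the 10 measured genes of the surrounding Dlk1-Dio3 imprinted region, only Dio3 and Dio3os rose. Meg3, a maternally expressed non-coding RNA, fell from 40.5 to 27.5 RPKM, and Rtl1 fell from 2.38 to 1.80 RPKM. Rian (82.9 and 70.7 RPKM) and Dlk1 (46.9 and 37.7 RPKM) did not pass, and neither did the other 4 members. The moderated limma test called 2 members higher and 5 lower, both over all genes tested and adjusted over the list alone. The median log2 ratio of the region was -0.20, its mean was 0.22 and its set test pointed down, so that median and mean differed in sign.

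By size alone, 237 genes were at least 2-fold higher and 113 at least 2-fold lower in Dio3KO-labelled testes. Of these, 215 and 88 also had an adjusted p below 0.05 in the authors' deposited table. Without the limit on fold, 2127 genes rose and 2421 fell, so most differences were smaller than 2-fold. In the same comparison the markers of macrophages were higher, with a median log2 ratio of 0.90, and those of endothelial cells were higher at 0.42, while cell cycle genes were lower at -0.64. On the scale of log2(RPKM + 0.5), the largest rise was that of Drd4, a dopamine receptor, from 2.72 RPKM (CV 0.42) to 38.5 RPKM (CV 0.16), with an adjusted p of 0.0111 in the authors' deposited table. Art3, an ADP-ribosyltransferase family member, rose from 8.73 to 68.5 RPKM. Rasl10a, a Ras-like GTPase, rose from 3.69 to 34.7 RPKM and Lrp8, a receptor for apolipoprotein E and reelin, from 2.44 to 24.3 RPKM. B4galnt1, which makes complex gangliosides, rose from 1.16 to 14.0 RPKM, Acp7 from 2.14 to 17.9 RPKM, Myoz2 from 1.86 to 15.4 RPKM and the lysophosphatidic acid receptor Lpar3 from 1.45 to 11.2 RPKM. A transcript whose symbol had been turned into a date in September rose from 1.66 to 17.6 RPKM. Hsd3b6, a steroid dehydrogenase, rose from 0.14 to 5.26 RPKM. Wfdc18 had means of 0.21 and 7.20 RPKM but an adjusted p of 0.0743 in the authors' deposited table.

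Among the genes with the deepest falls, Hsd17b3, the enzyme that makes testosterone from androstenedione, fell from 117 RPKM (CV 0.13) to 10.3 RPKM (CV 0.51), a log2 ratio of -3.45 ± 0.36 (SE computed from the CVs), with an adjusted p of 0.0065 in the authors' deposited table. Ptgds, a prostaglandin D synthase, fell from 45.4 to 3.52 RPKM and Hsd17b1, another 17-beta-hydroxysteroid dehydrogenase, from 73.9 to 14.1 RPKM. The glutathione transferases Gsta2 and Gsta1 fell from 40.8 to 4.72 RPKM and from 13.9 to 1.63 RPKM. These are close paralogs, and reads shared between them could not be separated here. The defensin Defb42 fell from 12.7 to 1.34 RPKM, and the secreted protease Adamts16 from 9.52 to 0.73 RPKM. A transcript listed as mKIAA2029, a symbol not matched to the reference, had nearly the values of Adamts16 (8.86 and 0.67 RPKM) and cannot be counted as a separate gene. Pnmt, the enzyme that makes adrenaline, had the largest ratio of means, 11.9 against 0.34 RPKM, but varied widely within groups (CV 0.43 and 0.54) and had an adjusted p of 0.0625 in the authors' deposited table. Cbln4 (5.14 and 0.34 RPKM), Cbln1 (13.9 and 2.31 RPKM) and Cyp11b1 (3.54 and 0.13 RPKM) did not pass either. The moderated limma test, which works on the log2 scale and pools the spread across genes, did call these genes. On that scale the ratio of Pnmt was -3.89 ± 0.34 (SE computed from the CVs) before any pooling. The limma adjusted p values were 1.67e-05 for Pnmt, 3.88e-05 for Cbln4, 0.000223 for Cbln1 and 0.000481 for Cyp11b1, and 2.19e-05 for Wfdc18. Of the genes at least 2-fold different, the moderated limma test called 237 higher and 108 lower. Without the limit on fold it called 2837 higher and 3533 lower, 6370 of 15225 genes. Its counts within each list are to be read against that share.

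Genes known from other tissues to respond to thyroid hormone were higher as a group. Of 22 measured members, 12 rose, 1 fell and 9 did not pass, and the moderated limma test called 12 higher and 1 lower, both over all genes tested and adjusted over the list alone. Klf9, a transcription factor induced by thyroid hormone in brain, rose from 8.17 RPKM (CV 0.19) to 34.5 RPKM (CV 0.05), with an adjusted p of 0.0022 in the authors' deposited table and a log2 ratio of 2.01 ± 0.13 (SE computed from the CVs). Hr, a nuclear receptor corepressor, rose from 1.14 to 7.66 RPKM, Bcl3, a coactivator of NF-kappa-B, from 2.36 to 9.55 RPKM, and Cpt1a, which admits fatty acids to mitochondria, from 46.1 to 65.0 RPKM. Mbp, a myelin protein, was the member that fell, from 4.40 to 2.39 RPKM. Aldh1a1 (560 and 575 RPKM) and Me1 (133 and 145 RPKM) did not pass. The median log2 ratio of the list was 0.33, above the central 95% of 10000 random lists of the same size and level (-0.16 to 0.09).

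Of 18 measured genes of thyroid hormone metabolism, transport and receptors, 6 rose, 1 fell and 11 did not pass. The receptor gene Thra fell from 133 to 107 RPKM, while Thrb, expressed far lower, rose from 1.80 to 3.03 RPKM. Slco1a4, an organic anion transporter, rose from 0.64 to 1.49 RPKM, the sulfotransferase Sult1a1 from 17.2 to 23.0 RPKM, and Dio3 is also counted here. The amino acid transporter subunits Slc7a5 (106 and 99.4 RPKM) and Slc3a2 (81.4 and 81.6 RPKM) did not pass. The moderated limma test called 6 higher and 3 lower, both over all genes tested and adjusted over the list alone, and the list median of 0.00 lay within the range of random lists.

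**Figure D1:**
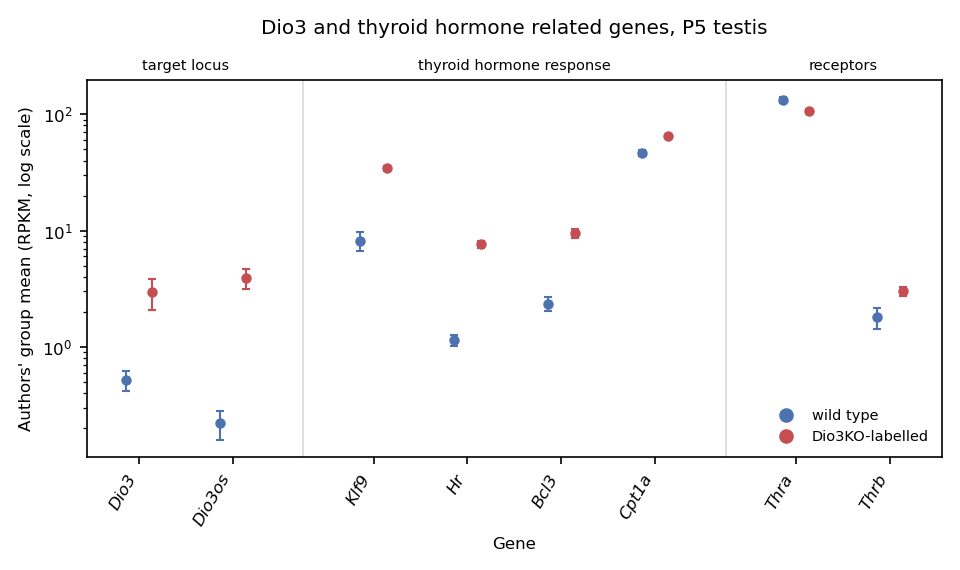
The plot shows the authors' group mean in RPKM (log axis) of genes at the Dio3 locus, of 4 thyroid hormone response genes and of the receptors Thra and Thrb in wild-type and Dio3KO-labelled testes at postnatal day 5, with bars of 1 SD (mean times CV). Dio3, Dio3os and Klf9 lie higher in the Dio3KO-labelled group (Klf9 34.5 against 8.17 RPKM), and Thra lies slightly lower (107 against 133 RPKM).

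Genes of the Leydig cell lists moved in opposite directions. In the list of fetal Leydig cell genes, all 5 members that passed, of 9 measured, fell and 0 rose. Values of whole testes do not show in which cells a listed gene was expressed. Besides Adamts16, Hsd17b1 and Gsta2, given above, the renin gene Ren1 fell from 15.0 RPKM (CV 0.06) to 5.74 RPKM (CV 0.06), with an adjusted p of 0.0043 in the authors' deposited table, and the aldo-keto reductase Akr1b7 fell from 12.2 to 7.84 RPKM. Dlk1 and Thbs2 (37.3 and 30.6 RPKM) did not pass. The median log2 ratio was -1.31, below that of the random lists (-0.20 to 0.17), and the moderated limma test called 8 lower over all genes tested and 8 adjusted over the list alone. Of 11 adult Leydig cell genes, 5 rose and 4 fell. The risers were Hsd3b6, the adhesion molecule Vcam1 (21.2 to 40.5 RPKM), the steroid reductase Srd5a1 (3.49 to 6.45 RPKM) and, named after their values were seen, Itih2 (2.06 to 2.72 RPKM) and the prolactin receptor Prlr (5.79 to 10.7 RPKM). Those that fell were Hsd17b3, Ptgds, Akr1c14 (12.4 to 6.51 RPKM) and, also named after its value was seen, Gsta3 (18.3 to 10.7 RPKM). Hsd17b3 also stands in the list of immature Sertoli cells and Ptgds in that of Sertoli cell identity. Neither of these falls can therefore be placed in Leydig cells here. Amhr2 (132 and 178 RPKM) and Insl3 (84.7 and 70.01 RPKM) did not pass. Its median log2 ratio was 0.33 but its mean was -0.21, and with no filter on low values the median turned to -0.03. With the moderated limma test, 6 were called higher and 4 lower over all genes tested, and 6 and 5 adjusted over the list alone.

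In the list of steroidogenesis and Leydig cell function, 11 of 28 members rose and 7 fell. Cyp11a1, the side-chain cleavage enzyme that starts steroid synthesis, rose from 64.2 RPKM (CV 0.11) to 156 RPKM (CV 0.10), with an adjusted p of 0.0074 in the authors' deposited table and a log2 ratio of 1.28 ± 0.11 (SE computed from the CVs). Soat1, which esterifies cholesterol for storage, rose from 35.2 to 71.0 RPKM. Hsd17b3 and Akr1c14 fell, and Cyp17a1 was at 55.5 RPKM (CV 0.37) and 55.1 RPKM (CV 0.13), an adjusted p of 0.7898 in the authors' deposited table. The list's median log2 ratio was 0.15 and its mean -0.05, and the moderated limma test called 13 higher and 8 lower over all genes tested, against 13 and 9 adjusted over the list alone. Of 24 cholesterol synthesis genes, 5 rose and 0 fell, among them Msmo1 (37.8 to 51.3 RPKM), Sc5d (10.7 to 14.0 RPKM), Tm7sf2 (4.42 to 5.57 RPKM), Nsdhl (10.1 to 11.5 RPKM) and, named after its value was seen, Hmgcs1 (115 to 139 RPKM). Fdps (102 and 98.9 RPKM) and Insig1 (50.5 and 51.7 RPKM) did not pass, the median log2 ratio was 0.06, and the moderated limma test called 5 higher and 1 lower over all genes tested and adjusted over the list alone.

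**Figure D2:**
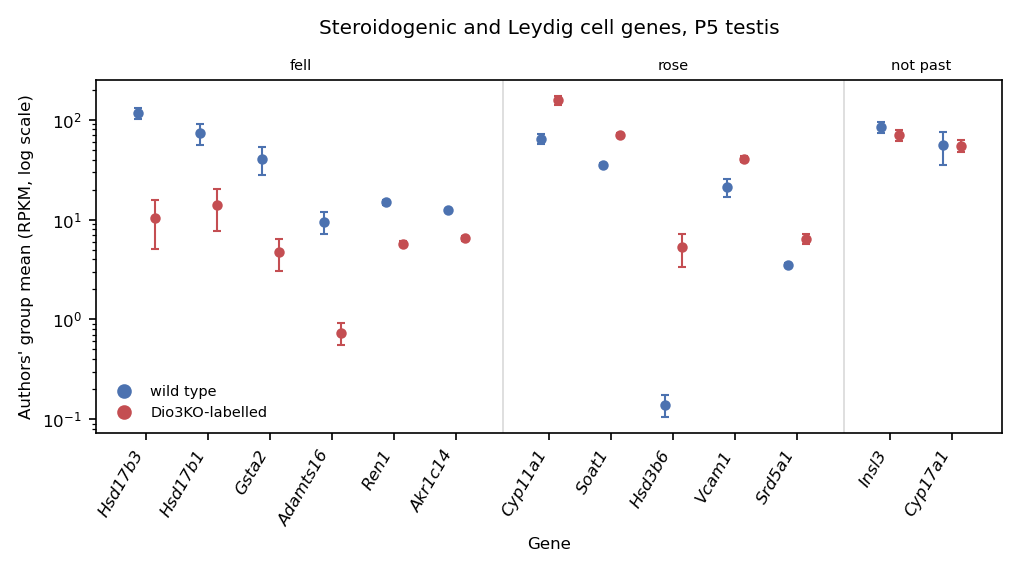
The plot shows the authors' group mean in RPKM (log axis) of 13 steroidogenic and Leydig cell genes in wild-type and Dio3KO-labelled testes, grouped by whether they fell, rose or did not pass in the authors' deposited table, with bars of 1 SD (mean times CV). Hsd17b3, which also stands in the immature Sertoli cell list, lies lower in the Dio3KO-labelled group (10.3 against 117 RPKM). Cyp11a1 lies higher (156 against 64.2 RPKM) and Cyp17a1 overlaps.

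Sertoli cell genes did not move as a block. Of 29 genes of Sertoli cell identity, 6 rose, 8 fell and 15 did not pass, with a median log2 ratio of 0.03 and a mean of -0.09. Amh, the anti-Müllerian hormone made by immature Sertoli cells, fell from 284 RPKM (CV 0.12) to 127 RPKM (CV 0.12), with an adjusted p of 0.0094 in the authors' deposited table, and the receptor gene Fshr fell from 17.8 to 9.49 RPKM. Cldn11, a tight junction protein of Sertoli cells, rose from 83.6 RPKM (CV 0.27) to 300 RPKM (CV 0.09), with an adjusted p of 0.003 in the authors' deposited table, and Tsx rose from 1.17 to 2.90 RPKM. Ctsl (601 and 611 RPKM) and Cst12 (477 and 494 RPKM) did not pass, and the moderated limma test called 7 higher and 8 lower, both over all genes tested and adjusted over the list alone.

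Split by stage, the lists parted. Of 16 genes of immature Sertoli cells, 0 rose and 7 fell. Apart from Amh, Hsd17b3 and Thra, the mitotic kinase Aurkb fell from 36.5 to 20.5 RPKM, while Dlk1 and Nr0b1 (21.96 and 28.3 RPKM) did not pass. Its median log2 ratio was -0.56, and the moderated limma test called 0 higher and 12 lower over all genes tested, and 1 and 12 adjusted over the list alone. Of 22 genes of maturing Sertoli cells, 12 rose and 2 fell, with a median log2 ratio of 0.39. The drug efflux transporter Abcb1a rose from 2.06 to 4.74 RPKM. Fabp5 fell from 61.2 to 35.9 RPKM, and so did the gap junction gene Gja1, named after its value was seen, from 163 to 91.7 RPKM. Defb19 (383 and 521 RPKM) and Fyn (53.3 and 59.1 RPKM) did not pass. Under the moderated limma test, 14 were called higher and 2 lower over all genes tested, and 16 and 2 adjusted over the list alone.

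Of 26 genes of tight and gap junctions, 12 rose and 5 fell, with a median log2 ratio of 0.24. Besides Cldn11, Cldn7 rose from 0.86 to 3.8 RPKM, while Cldn1 fell from 14.2 to 9.53 RPKM. The others that fell, named after their values were seen, were Gja1, Marveld2 (8.33 to 6.12 RPKM), Cdh3 (34.2 to 9.96 RPKM) and Pard3 (12.3 to 10.1 RPKM). F11r (79.4 and 98.2 RPKM) and Cgn (35.5 and 49.2 RPKM) did not pass, and the moderated limma test called 14 higher and 7 lower, both over all genes tested and adjusted over the list alone. Among 39 genes of gonadal hormone receptors and growth factors, 9 rose and 9 fell. Bmp4 rose from 5.52 to 9.27 RPKM, whereas Wnt6 fell from 94.8 to 50.7 RPKM and the retinol transporter Stra6 from 10.97 to 5.52 RPKM. Inha, an inhibin subunit, was at 435 and 455 RPKM and did not pass. The median log2 ratio was 0.07 and the mean -0.01, and the moderated limma test called 13 higher and 12 lower over all genes tested, and 14 and 12 adjusted over the list alone.

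Genes of the cell cycle fell almost as a whole. Of 44 measured members, 41 fell, 1 rose and 2 did not pass, and the moderated limma test called 43 lower and 1 higher, both over all genes tested and adjusted over the list alone. Top2a, the topoisomerase of dividing cells, fell from 119 RPKM (CV 0.04) to 71.4 RPKM (CV 0.07), with an adjusted p of 0.0025 in the authors' deposited table and a log2 ratio of -0.73 ± 0.06 (SE computed from the CVs). Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, fell from 66.3 to 30.1 RPKM, and the spindle genes Kif11 and Tpx2 fell from 42.3 to 23.7 RPKM and from 30.8 to 19.7 RPKM. Ccnd1, named after its value was seen, rose from 9.29 to 10.97 RPKM, and Ccnd2 (58.9 and 45.0 RPKM) and Cdk2 (45.3 and 40.1 RPKM) did not pass. The list median was -0.64, against -0.11 to 0.04 for random lists. Of 16 genes of CDK inhibition and cell cycle exit, 5 rose and 3 fell. Rb1 rose from 11.3 to 13.7 RPKM and Btg2 from 17.5 to 22.2 RPKM, as did Gadd45a (7.77 to 16.5 RPKM), Gadd45b (9.04 to 15.1 RPKM) and Rbl2 (12.4 to 15.7 RPKM), named after their values were seen. Rbl1 fell from 12.4 to 7.27 RPKM, Cdkn2c from 28.8 to 16.4 RPKM and Ccng2, named after its value was seen, from 22.8 to 18.5 RPKM. Cdkn1c (24.0 and 24.7 RPKM) and Ccng1 (25.3 and 28.4 RPKM) did not pass, the median was 0.05, and the moderated limma test called 6 higher and 3 lower, both over all genes tested and adjusted over the list alone.

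Of 25 genes found across germ cell stages, only Dnmt3a passed, rising from 30.8 to 33.6 RPKM, while Tuba3a (403 and 383 RPKM) and Tuba3b (146 and 119 RPKM) did not. The median log2 ratio was -0.15, and the moderated limma test called 0 higher and 4 lower over all genes tested, and 0 and 0 adjusted over the list alone. Of 21 genes of undifferentiated spermatogonia, 4 fell and 0 rose, with a median of -0.28, below that of random lists (-0.17 to 0.10). The GDNF receptor gene Ret fell from 9.43 to 6.69 RPKM, Bcl6b from 5.89 to 3.50 RPKM, Egr2 from 3.88 to 2.11 RPKM and Tspan8 from 3.28 to 2.19 RPKM, while Itga6 (71.7 and 80.7 RPKM) and Etv5 (23.2 and 24.3 RPKM) did not pass. The moderated limma test called 1 higher and 7 lower, both over all genes tested and adjusted over the list alone. Of 26 genes of differentiating spermatogonia and meiosis, 2 fell and 0 rose, among them Syce2 (26.0 to 18.3 RPKM). Sycp3 (17.8 and 24.7 RPKM) and Sohlh1 (18.8 and 18.8 RPKM) did not pass, the median was 0.02, and the moderated limma test called 3 higher and 2 lower, both over all genes tested and adjusted over the list alone.

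Markers of macrophages and other leukocytes were higher. Of 20 measured members, 15 rose and 0 fell, with a median log2 ratio of 0.90. Csf1r, the receptor for the macrophage growth factor, rose from 7.85 RPKM (CV 0.10) to 15.9 RPKM (CV 0.08), with an adjusted p of 0.005 in the authors' deposited table, and Cx3cr1, Tyrobp and Fcer1g rose from 4.06 to 9.11 RPKM, from 9.44 to 17.9 RPKM and from 5.55 to 10.4 RPKM. Lyz2 (24.2 and 41.2 RPKM) and the mast cell protease Mcpt4 (10.6 and 12.1 RPKM) did not pass. With the moderated limma test, 17 were called higher and 0 lower, both over all genes tested and adjusted over the list alone. Of 20 endothelial markers, 11 rose and 0 fell, with a median of 0.42. Ptprb rose from 1.86 to 3.76 RPKM, Tek from 2.66 to 4.25 RPKM, Cldn5 from 7.29 to 13.3 RPKM and Esam from 6.56 to 9.81 RPKM, while Cdh5 (23.5 and 24.4 RPKM) and Sox18 (14.5 and 10.6 RPKM) did not pass. Under the moderated limma test, 14 were called higher and 2 lower over all genes tested, and 16 and 2 adjusted over the list alone.

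Peritubular myoid genes went both ways, with 5 of 18 rising, 2 falling and a median log2 ratio of 0.02. Des rose from 13.8 to 25.3 RPKM, Mylk from 89.2 to 106 RPKM and Lmod1 from 5.78 to 7.03 RPKM, as did Myh11 (57.5 to 66.5 RPKM) and Itga8 (7.82 to 10.1 RPKM), named after their values were seen. Acta2 fell from 401 to 346 RPKM and Gli1, named after its value was seen, from 16.8 to 13.8 RPKM. Myl9 (268 and 265 RPKM) and Tpm1 (209 and 193 RPKM) did not pass, and the moderated limma test called 5 higher and 3 lower, both over all genes tested and adjusted over the list alone. Of 42 extracellular matrix genes, 10 rose and 0 fell, with a median of 0.14. Sparc rose from 888 to 1278 RPKM, and the basement membrane collagens Col4a3, Col4a5 and Col18a1 rose from 21 to 34.6 RPKM, from 24.2 to 41.4 RPKM and from 102 to 134 RPKM. Col3a1 (778 and 1071 RPKM) and Col1a2 (637 and 915 RPKM) did not pass. The moderated limma test called 13 higher and 4 lower over all genes tested, and 13 and 6 adjusted over the list alone.

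Tissue and source were labelled testis, whereas the extraction text speaks of hypothalami. The medians over Sertoli cell genes were 82.1 and 67.1 RPKM, whereas 7 of 22 brain and hypothalamus genes reached 1 RPKM in wild-type testes and 4 in Dio3KO-labelled testes. Tubb3, a neuronal tubulin, rose from 48.5 to 131 RPKM. Mbp, Pmch (1.89 to 1.05 RPKM) and Syt1 (1.43 to 0.74 RPKM) fell, and Agrp (1.49 and 0.77 RPKM) did not pass. With the moderated limma test, 1 were called higher and 5 lower in this list, both over all genes tested and adjusted over the list alone, and the median log2 ratio was -0.64. Red blood cell genes were abundant and variable, with Hba-a2 at 727 RPKM (CV 0.53) and 611 RPKM (CV 0.16) and Hbb-bs at 710 RPKM (CV 0.57) and 649 RPKM (CV 0.16), and 0 of 5 passed, by either the deposited p or the moderated limma test, over all genes tested or adjusted over the list alone. Their median was -0.14. Of 8 genes of the epididymis and mesonephric remnants, Pax8 rose from 0.66 to 1.89 RPKM and Hoxd10 fell from 10.3 to 6.55 RPKM, while Epcam (12.2 and 12.3 RPKM) and Krt19 (3.58 and 4.04 RPKM) did not pass, with a median of 0.36. Of 4 fat cell genes, Pparg rose from 0.51 to 1.62 RPKM, and Lpl (10.7 and 15.2 RPKM) and Plin1 (9.84 and 12.3 RPKM) did not pass, with a median of 0.40. Of 6 skeletal muscle genes, Des and Actn3 (1.40 to 2.87 RPKM) rose, and Myh8 (3.18 and 2.81 RPKM) and Tnni2 (2.52 and 3.08 RPKM) did not pass, with a median of 0.21. Under the moderated limma test, 3 were called higher and 1 lower in the epididymal list, 3 and 0 in the fat list and 2 and 0 in the muscle list, the same over all genes tested and adjusted over the list alone.

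Of 20 immediate early and heat shock genes, 3 rose and 3 fell, with a median log2 ratio of -0.05 and a mean of 0.08. Atf3 rose from 2.78 to 8.58 RPKM, Fos from 1.75 to 2.71 RPKM and Jun, named after its value was seen, from 22.1 to 26.9 RPKM. Hspb1 fell from 139 to 110 RPKM, Egr2 fell as given above, and Dnajb1, named after its value was seen, fell from 28.1 to 21.8 RPKM. Hspa8 (957 and 861 RPKM) and Jund (109 and 96.2 RPKM) did not pass, and the moderated limma test called 5 higher and 5 lower over all genes tested, and 5 and 7 adjusted over the list alone. Among 49 nuclear genes of oxidative phosphorylation, 2 rose, 2 fell and 45 did not pass. Cycs, cytochrome c, rose from 111 to 164 RPKM and Ndufs1 from 41.8 to 43.6 RPKM, while Cox7b fell from 57.3 to 50.5 RPKM and Cox7c from 279 to 244 RPKM. Atp5b (494 and 466 RPKM) and Cox4i1 (381 and 346 RPKM) did not pass. The median was -0.09, and the moderated limma test called 2 higher and 9 lower over all genes tested, and 2 and 8 adjusted over the list alone. Ndufs1 was not among those it called over all genes tested (limma adjusted p = 0.244).

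**Figure D3:**
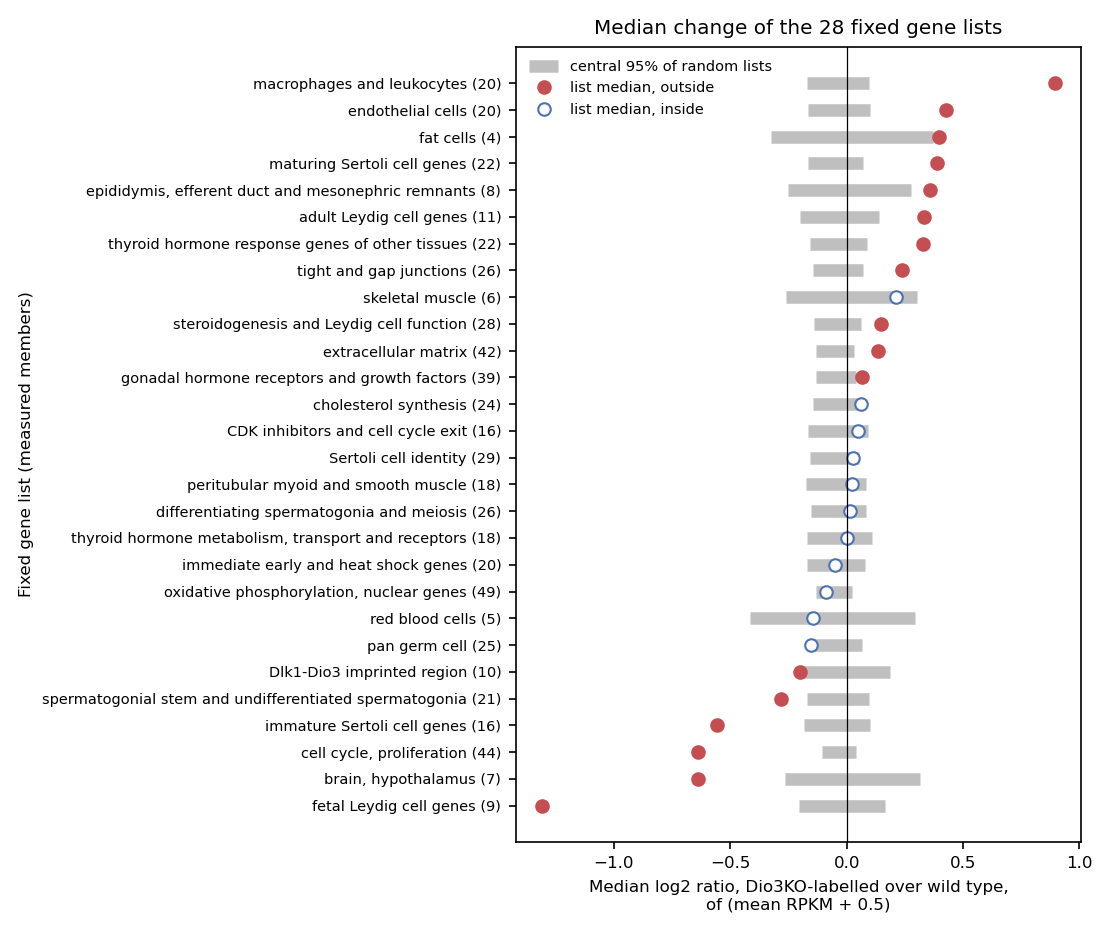
The plot gives, for each of 28 gene lists (number of measured members in brackets), the median log2 ratio of Dio3KO-labelled over wild-type means as a point and the central 95% of 10000 random lists of the same size and level as a grey bar. The medians of macrophage genes (0.90) and fetal Leydig cell genes (-1.31) lie farthest from their bars, and 17 lists lie outside.

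As a set, 9 of the 28 lists passed limma's preranked camera test with a preset correlation between genes of 0.01. The lower lists were the cell cycle (adjusted p = 1.09e-19 in limma's test), fetal Leydig cells (8.46e-05) and immature Sertoli cells (0.000401). The higher lists were macrophages (adjusted p = 2.92e-10 in limma's test), thyroid hormone response (8.14e-07), endothelium (1.87e-05), maturing Sertoli cells (0.000241), extracellular matrix (0.00665) and tight and gap junctions (0.0228). With a preset correlation of 0.05, the matrix list (limma adjusted p = 0.121) and the junction list (limma adjusted p = 0.142) no longer passed, while the other 7 did. Steroidogenesis, germ cell, myoid and the remaining lists did not pass at either setting. An estimated correlation needs values per sample, so which calls would hold with one is unknown. These p values of lists set a list's genes against the other genes under an assumed correlation. The p values of single genes measure the spread between these samples, which the labels call biological replicates, and how many single mice showed a direction could not be counted.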

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

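The choice of transcript, the counting of every transcript, the moderated limma test and the second preset correlation were added after the data were seen, and the other alternatives were planned. Of the counts of genes at least 2-fold different (350 in all), those under both other pseudocounts, no filter, centring at 0, another transcript per gene and the added demand of a small adjusted p stayed within 1.5 times. With a filter of 5 RPKM the count was 209 (151 higher, 58 lower), because fewer genes were eligible. With a fold of 1.5 it was 1406 (846 higher, 560 lower), since the threshold was wider. With every transcript counted it was 638 (461 higher, 177 lower), and 4853 transcripts rose and 5499 fell by the authors' p-values, since genes with several transcripts counted more than once. The log2 ratio of Dio3 ran from 1.38 to 2.30 over its alternatives and had no value under the filter of 5 RPKM. Lists with a median outside that of random lists numbered from 13 to 18 over the alternatives. Among list medians recomputed, 177 kept their sign and side, 5 passed anew, 9 no longer passed and 1 reversed. The reversed median was that of adult Leydig cells, at -0.028 with no filter on low values. Its 11 measured members kept their ratios there, so the reversal came from added members below 1 RPKM in both groups. Among the log2 ratios of named genes recomputed, 1057 kept their sign and side of 2-fold, 3 passed it anew and 8 no longer did. No scaling moved the median log2 ratio of all genes by over 0.1. No paired analysis was possible because the columns hold group means and carry no replicate number. For the same reason leaving out single samples, quantile normalization, array weights, other variance models, an estimated correlation, a permutation test of Dio3 and other splits of the samples could not be run, and the alternatives for raw counts did not apply. Depth is unknown, so how far it limits the low genes, Dio3 among them, could not be said.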

Other observations

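All tests and genes of this part, and the grouping of genes by symbol, were chosen after the results were seen. The 218 groups of genes that share a symbol stem, some of which overlap the fixed lists, were searched with limma's preranked camera test at a preset correlation of 0.05. Genes with the histone stem Hist were lower, with a median log2 ratio of -0.91 over 62 genes (limma adjusted p = 3.62e-09). Several of them had nearly equal values (Hist1h2ah 2411 to 1319 RPKM, Hist1h2ai 2410 to 1320 RPKM). Neither the count nor the limma adjusted p therefore rests on 62 separate observations. The stem Rpl, of large ribosomal subunit proteins and a few of their pseudogenes, was at -0.40 over 52 genes (limma adjusted p = 1.75e-06). The stem Rps was at -0.41 over 44 genes (limma adjusted p = 0.00111), but holds kinases named for a ribosomal substrate and pseudogenes beside the small subunit proteins. The Mcm genes, most of which encode the replicative helicase, were at -0.55 (limma adjusted p = 0.00149), several of them also in the cell cycle list, and nucleoporins at -0.29 (limma adjusted p = 0.0445). Claudins, most of which also stand in the junction list, were higher, at 0.82 over 9 genes (limma adjusted p = 0.035). UDP-glucuronosyltransferases, enzymes that conjugate steroids and thyroid hormones, were higher at 0.80 over 9 genes (limma adjusted p = 0.000144), but the Ugt1a genes among them share exons and had nearly equal values (Ugt1a1 5.67 to 10.3 RPKM, Ugt1a2 5.72 to 10.3 RPKM), so they count as about 1 observation. No other group passed.

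Genes tied to adrenal hormone synthesis were unevenly expressed. Pnmt was at 11.9 RPKM in wild-type and 0.34 RPKM in Dio3KO-labelled testes, while Th and Dbh, which act before it on the way to adrenaline, were at 0.06 and 0.10 RPKM and at 0.04 and 0.01 RPKM. Cyp21a1, of corticosteroid synthesis, fell from 11.98 to 4.80 RPKM, and Cyp11b1 was at 3.54 and 0.13 RPKM. Replicates were also more alike in 1 group than in the other. Among 10675 genes above 5 RPKM in both groups, the median CV was 0.07 in wild type and 0.05 in Dio3KO-labelled testes, and the wild-type CV was the higher in 59.7% of genes. Of these, the 71 genes at least 2-fold higher had median CVs of 0.18 in wild type and 0.11 in Dio3KO-labelled testes, and the 31 genes at least 2-fold lower had 0.08 and 0.15.

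Dio3 and Dio3os were higher in the group labelled as lacking Dio3. Exchanged columns would turn every direction round and place the thyroid hormone response genes lower in the true knockout, in which less hormone should be inactivated. As labelled, their median log2 ratio was 0.326 (95% bootstrap interval over genes 0.148 to 0.647), which argues against an exchange. That list had already been seen to be higher, so this is not a separate test. It also rests on these genes of other tissues responding alike in the neonatal testis. A rise of the whole region in cis is argued against by the other 24 measured genes within 1 Mb. Of these, 2 rose and 2 fell, with a median of -0.176 (-0.278 to -0.112), below the median of -0.049 over all genes. A cis effect of opposite sign on the neighbours, or one limited to Dio3 and Dio3os, was not tested and stays open. An altered allele that is still transcribed, and whose transcription may respond to more thyroid hormone, stays open and was not tested, since no values for parts of the gene were at hand.

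Macrophage and endothelial markers were higher together. A lower share of 1 main cell type other than germ cells would raise all remaining types alike. Against this, the median of macrophage markers exceeded that of germ cell markers by 1.049 (95% bootstrap interval over genes 0.879 to 1.219) and that of endothelial markers by 0.471 (0.265 to 0.714). A lower share of germ cells together with other cells would also set macrophage markers above germ cell markers, so a wider shift in composition stays open. More blood left in the tissue is argued against only as the source of the whole rise of the macrophage markers. The median log2 ratio of red blood cell genes was -0.144. The highest of them, with 2 standard errors added, reached 0.723, below the macrophage median of 0.896. A smaller rise of these variable genes lies within that range, so blood as a part of the account stays open. For the endothelial markers, at 0.425, that range excludes nothing. A larger share of macrophages, or more of these transcripts in each, also stay open as hypotheses tied to the genotype label and were not tested. RPKM values are relative and do not give a number of cells per testis.

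Genes of ribosomal proteins and histones, here without pseudogenes and kinases, were lower, with 82 of 82 and 61 of 61 measured genes having the lower mean in Dio3KO-labelled testes, 76 and 56 of which fell by the authors' deposited table. Genes matched on longest annotated transcript and level had medians of -0.078 (-0.13 to 0.009) and -0.088 (-0.14 to -0.013). The families were at -0.42 and -0.91, which argues against short transcripts and high levels as the account, as far as the match reached. How close the matched genes came to the families' medians of 715 and 1336 RPKM in wild type is not known here. Histone transcripts mostly lack a poly(A) tail, but 77 structural RNAs that also lack one had a median of -0.172 (-0.294 to -0.046). A lower yield shared alike by all such RNAs therefore does not account for the histone fall as a whole. Whether the libraries captured these structural RNAs and histone transcripts alike is unknown, so a loss particular to histone transcripts stays open. The 12 DNA replication genes of the cell cycle list had a median of -0.554 (-0.591 to -0.438). That list had already been seen to be lower, so these values are not a separate test. Fewer cells copying their DNA may lie behind the histone genes, as a hypothesis found on the same data. For the ribosomal proteins no biological explanation was tested, and reads shared with pseudogenes or near-identical copies stay open for both families. Several histone genes had nearly equal values, so the count of 61 overstates the separate observations.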
